A study of Homo sapiens with 8 samples.

How the data were processed

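Small RNA libraries of 2 human cell lines were analysed: MCF7, a breast adenocarcinoma line, and HCT116, a colorectal carcinoma line. Each line was treated for 72 h with Akti-1/2, an allosteric inhibitor of the AKT kinases, or with its solvent DMSO. The dose was 2 µM in MCF7 and 20 µM in HCT116. Line and dose therefore changed together. Each of the 4 groups had 2 libraries, 8 in all. The labels number the replicates but do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Total RNA was purified on silica columns and made into libraries with a TruSeq small RNA kit followed by gel size selection, per the labels' protocols.

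The deposited table holds whole-number counts of reads per annotated feature, not normalized, in 1 column per library. Adapter trimming with cutadapt 1.2.1, alignment with Bowtie 1.0 and counting with HTSeq are named, without their order or settings, per the submitters' processing notes. The genome names given there are hg19 and GRCh37.p13. Strand setting and treatment of reads with several alignments are not given in the sources used here. The table's tally of non-unique alignments was 0 in all libraries, so reads of near-identical copies (miRNA genes with several copies, 5S rRNA pseudogenes, snRNA copies, the SNORD45 genes) are uncertain between copies. Overlapping and antisense features are uncertain for the same lack of settings.

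The table lists 35310 features, of which 3993 had a count above 0 in some library. The 5 tally rows of the counter were kept out of library sizes and tests. Reads in no feature made up 33.31% to 58.44% of the reads in features, in none, or ambiguous, and ambiguous reads numbered 1 to 46 per library. Symbols and RNA types were taken from GENCODE release 29 by Ensembl gene ID, which matched 30839 IDs. The other 4471 IDs, 373 of them above 0, were kept under their IDs. That annotation is on a later build than the deposited counts, so no coordinates are given.

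Counts were analysed with edgeR 4.0.16 in R 4.3.3. Features were filtered with filterByExpr by group, which left 565, and scaled by TMM, whose factors ran from 0.182 to 4.107. A model of the 4 group means was fitted to all 8 libraries with robust quasi-likelihood, and each comparison was tested with the quasi-likelihood F test, two-sided. The dispersion of each feature was estimated over all libraries of a fit together, so the 4 groups shared it. P-values were adjusted by Benjamini-Hochberg over all features tested, and a feature was called at an adjusted p under 0.05. The comparisons were Akti-1/2 against DMSO in each line, the difference of these effects (HCT116 minus MCF7), their mean, and HCT116 against MCF7 under DMSO. Fold changes are log2 with standard errors (SE). These errors were derived from the test, as the absolute fold change over the square root of its F, and were not estimated separately. A fitted fold change of a feature with a group at 0 depends on the prior count and is not a bound. For such features the summed counts of both groups, scaled by effective library size, are given with 3 counts over the group as the floor. Normalised CPM are CPM of the TMM-scaled library size.

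Fixed gene lists, 35 in number, were chosen before the data were examined: miRNA families and clusters, miRNAs known to target PTEN or AKT-mTOR genes, markers of each line and of other cell types, and classes of small RNA. Of these, 26 had a tested member and 21 had at least 3, and those were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 21 lists of a line. The design, the lists, the first set of alternative settings and the rule for named genes were also fixed before the data were examined. By that rule a within-line comparison names up to 10 called features each way with a mean of at least 10 normalised CPM and both treated libraries beyond both DMSO libraries. Where under 5 pass, it adds the 10 features of that abundance with the smallest unadjusted p. It also names the 5 most abundant features under DMSO and up to 4 members of each list. The difference and the mean effect name 10 features each by p, and the line comparison names the line markers and up to 5 called features each way.

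The alternatives were RLE, total-count and upper-quartile scaling, no abundance filter, at least 10 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, miRNAs alone, copies summed, and the libraries of one line (or the DMSO libraries) alone. Added after the data were seen were a lowess offset on GC content (span 0.5), features with a GC value alone, that offset with the replicate block, and a fit without 3 libraries whose line markers went against their labels. GC values, from GENCODE release 29 transcripts, existed for 90.8% of tested features. The fits were tested on simulated counts with 200 of 565 features changed.

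Gene counts per library ran from 10209682 to 16363224. Shares are given with 95% Wilson intervals, and a count of 0 allows up to 3 counts, or 0.183 to 0.294 CPM of the gene counts depending on the library. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.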

Results

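Small RNAs of MCF7 and HCT116 cells were sequenced after 72 h with Akti-1/2 or DMSO, in 2 libraries per group, to compare the small RNA profile of cells with and without AKT inhibition. Gene counts were 11583150 and 15554034 in the libraries labelled MCF7 Akti 1 and 2, and 16363224 and 15400458 in MCF7 DMSO 1 and 2. They were 15303032 and 10209682 in HCT116 Akti 1 and 2, and 11541246 and 11074452 in HCT116 DMSO 1 and 2. No pair of libraries was so close as to be a repeat deposit of the same library: the lowest chi-square per degree of freedom between the counts of a pair was 609.5. By that measure the closest pair joined different groups, MCF7 Akti 2 and MCF7 DMSO 1 (Pearson's r = 0.99, Spearman's rho = 0.948). By correlation the HCT116 DMSO pair was closest (r = 0.992, rho = 0.98). These correlations are across features, which are not independent replicates.

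The line comparison under DMSO asked which small RNAs distinguish the untreated lines. MIR31 (ENSG00000199177.1) and MIR100 (ENSG00000207994.1) were higher in HCT116, and MIRLET7C (ENSG00000199030.1) and SNORD45B (ENSG00000201487.1) were higher in MCF7. MIR31 had 9675 and 15149 reads in the HCT116 DMSO libraries against 0 and 1 in MCF7 DMSO, a ratio of summed normalised counts of 8010 (counting interval 1440 to 316000). MIR100 had 931 ± 33.3 normalised CPM in HCT116 DMSO and 0.197 ± 0.053 in MCF7 DMSO (SD, n = 2 each). MIRLET7C had 377 ± 132 in MCF7 DMSO and 0.346 ± 0.0533 in HCT116 DMSO. SNORD45B, a C/D box snoRNA of the class that guides 2'-O-methylation, had 9280 ± 10300 in MCF7 DMSO and 1.35 ± 0.0764 in HCT116 DMSO. These 4 of 565 features were called, 2 higher and 2 lower in HCT116, each at an adjusted p of 0.0348 by edgeR's quasi-likelihood test.

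Of the marker lists, MIR135B had 99 and 88 reads in the HCT116 DMSO libraries and 0 in both MCF7 DMSO libraries (at least 20.1-fold higher against a floor of 3 counts over the group), with an adjusted p of 0.0955 by edgeR. For the MCF7 markers MIR342, MIR653 and MIR190B the log2 difference, HCT116 minus MCF7, was -5.58 ± 1.88, -6.61 ± 2.32 and -6.38 ± 2.33 (SE). None of the 3 passed, each at an adjusted p of 0.0955 in edgeR's test. MIR375 had 28.1 ± 37.3 normalised CPM in MCF7 DMSO and 7.59 ± 0.62 in HCT116 DMSO (SD, n = 2 each). MIR196A1 and MIR196A2, listed as MCF7 markers, had log2 differences of 6.98 ± 2.61 and 2.85 ± 1.76 (SE) and did not pass. RLE or total-count scaling ended all 4 calls, and DESeq2 called 45 features. The DMSO libraries alone called 98, as did a fit without the 3 libraries described next. Leaving out 1 library gave 108 without either MCF7 Akti library, 107 and 25 without MCF7 DMSO 1 and 2, 0 and 45 without HCT116 Akti 1 and 2, and 2 without either HCT116 DMSO library.

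In 3 treated libraries these line-distinguishing RNAs went against the label. The library labelled MCF7 Akti 1 held 3723 reads of MIR31, 23052 of MIR100, 65748 of MIR10B and 137 of MIR135B, and 8 reads of MIRLET7C. The library labelled MCF7 Akti 2 held 0, 2, 103 and 0 reads of the first 4 and 3584 of MIRLET7C. The libraries labelled HCT116 Akti 1 and 2 held 3 and 0 reads of MIR31, 7 and 8 of MIR100, and 2111 and 759 of MIRLET7C. Over 28 features that separated the lines in the DMSO libraries by over 8-fold, 23 lay on the HCT116 side of the midpoint in the library labelled MCF7 Akti 1 and 0 in MCF7 Akti 2. On the MCF7 side lay 23 in the library labelled HCT116 Akti 1 and 22 in HCT116 Akti 2. Of the 10 features higher in MCF7, 9 lay on the MCF7 side in HCT116 Akti 1 and 5 in HCT116 Akti 2, at medians of 37.8% and 18.9% of their MCF7 DMSO level. Of the 18 features higher in HCT116, 4 stayed on the HCT116 side in HCT116 Akti 1 and 1 in HCT116 Akti 2. The 4 were H/ACA box snoRNAs: SNORA46, SNORA31 and SNORA26, at 37.1%, 30.6% and 29.9% of their HCT116 DMSO level, and SNORA53. SNORA53 followed the HCT116 label in both libraries, with 169 and 139 normalised CPM in the HCT116 Akti libraries, 123 and 128 in HCT116 DMSO, 35 in MCF7 Akti 1 and 0.586 to 1.8 in the other MCF7 libraries. The equal levels of the HCT116 groups depend on TMM: as CPM of the gene counts, SNORA53 had 95.5 and 25.4 in HCT116 Akti, 418 and 525 in HCT116 DMSO, 63.2 in MCF7 Akti 1 and 0.55 to 1.09 in the other MCF7 libraries. SNORA53 and MIR100 are set out here after their values were seen. Every direction given below for Akti-1/2 rests on libraries named by their labels, these 3 included.

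**Figure D1:**
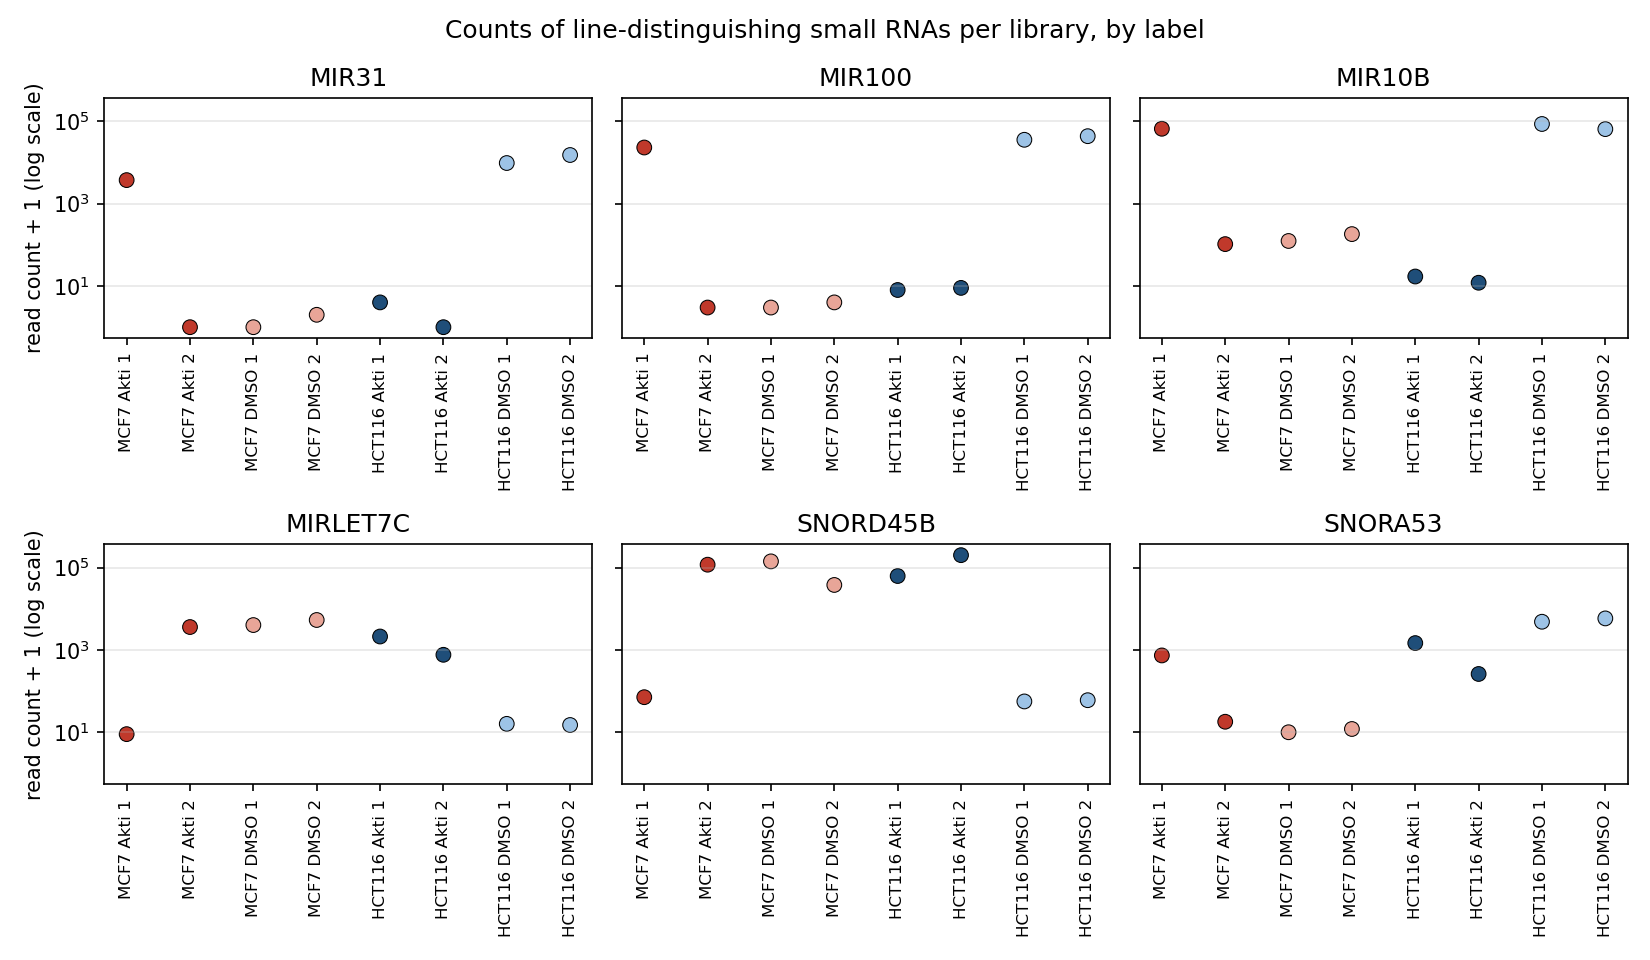
Read counts plus 1 (log axis) of 6 small RNAs in each of the 8 libraries, placed and coloured by labelled group, 1 point per library. MIR31, MIR100 and MIR10B are high in both HCT116 DMSO libraries and in the library labelled MCF7 Akti 1 (3723, 23052 and 65748 reads), MIRLET7C and SNORD45B are high in the other 5, and SNORA53 is above 100 reads in the 4 libraries labelled HCT116 and in MCF7 Akti 1.

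C/D box snoRNAs made up 90.9% to 97.9% of the gene counts in every library. SNORD61 alone took 14.95% of the counts in the library labelled MCF7 Akti 1, 60.32% in MCF7 Akti 2, 55.49% in MCF7 DMSO 1, 64.38% in HCT116 Akti 1 and 41.37% in HCT116 Akti 2. SNORD104 was the most abundant feature in MCF7 DMSO 2, at 40.09%, and in HCT116 DMSO 1 and 2, at 11.99% and 17.51%. The miRNA share was 1.69% ± 0.921 in MCF7 Akti and 2.56% ± 2.34 in MCF7 DMSO, and 0.323% ± 0.317 in HCT116 Akti and 4.23% ± 0.156 in HCT116 DMSO (SD, n = 2 each). In single libraries it ran from 0.0987% (95% Wilson interval 0.0967 to 0.101) in HCT116 Akti 2 to 4.34% (4.33 to 4.35) in HCT116 DMSO 2. Within MCF7 DMSO it was 0.903% (0.898 to 0.908) and 4.21% (4.2 to 4.22). IDs without a match, at 0.954% to 1.88% of the gene counts per library, may hold further miRNAs that this share leaves out. H/ACA box snoRNAs made up 0.0336% ± 0.03 in HCT116 Akti and 0.671% ± 0.166 in HCT116 DMSO, and 0.115% ± 0.138 in MCF7 Akti and 0.187% ± 0.246 in MCF7 DMSO. Shares are given as values: they were not fitted with a model, and an exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333.

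**Figure D2:**
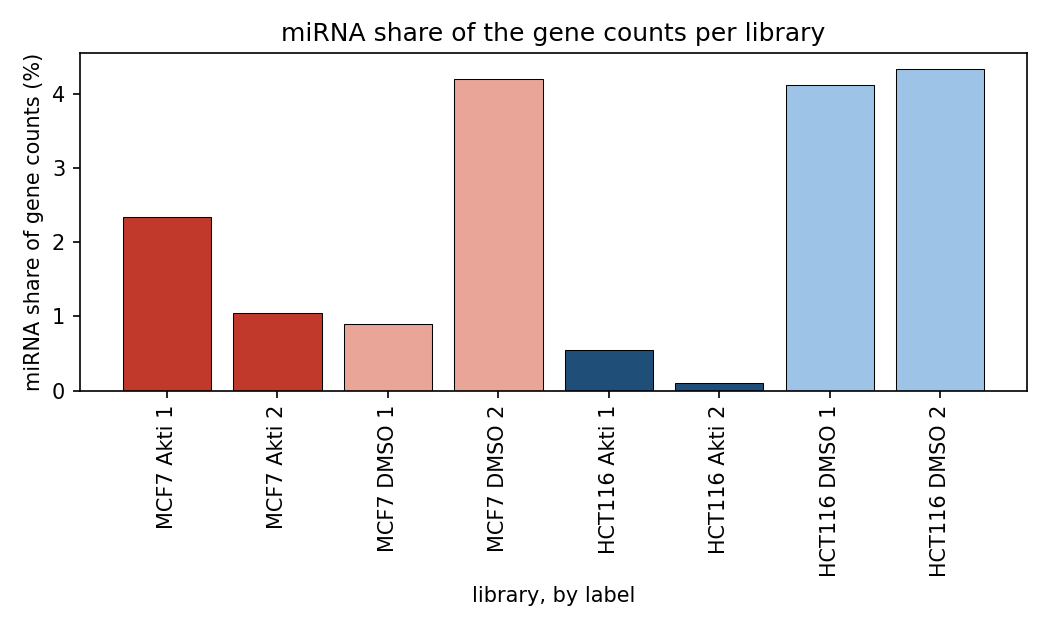
miRNA share of the gene counts (%, bars from 0) in each of the 8 libraries, coloured by labelled group. The MCF7 DMSO libraries lie at 0.903% and 4.21%, the HCT116 DMSO libraries at 4.12% and 4.34%, and the HCT116 Akti libraries at 0.547% and 0.0987%.

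In MCF7, the comparison asked which small RNAs changed with 2 µM Akti-1/2, and no feature passed the test. The smallest unadjusted p belonged to MIR100 and MIR31, whose treated values came from the library labelled MCF7 Akti 1. MIR100 had 1100 normalised CPM there, 0.211 in MCF7 Akti 2, and 0.235 and 0.16 in the DMSO libraries (log2 fold change 11.43 ± 2.73 SE, adjusted p = 0.131 by edgeR). MIR10B had 3140 and 10.9 in the treated libraries and 14.4 and 9.65 in the DMSO libraries. SNORD55, SCARNA22, SNORD105B, SNORA2C, SNORA64 and the unnamed ENSG00000221767.1 had log2 fold changes from -10.39 to -7.1, and SNORD54 had 6.85, again from the library labelled MCF7 Akti 1 (5662 reads against 2 in MCF7 Akti 2). The SNORD55 value rested on MCF7 DMSO 2, with 14298 reads against 0 in MCF7 DMSO 1, and 7 and 2 in the treated libraries. SCARNA22 likewise had 1235 reads in MCF7 DMSO 2 and 0 in MCF7 DMSO 1. The values of SNORD105B, SNORA2C, SNORA64 and ENSG00000221767.1 rested on MCF7 DMSO 2 as well. They had 83121, 42101, 3702 and 1749 reads there and 14, 10, 0 and 1 in MCF7 DMSO 1.

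The abundant C/D box snoRNAs of MCF7 had small fitted values with wide errors: the log2 fold change was -0.22 ± 1.6 for SNORD61, -0.16 ± 1.57 for SNORD45A, -0.04 ± 1.59 for SNORD45C and -0.12 ± 1.56 for SNORD5 (SE). SNORD104 had -5.79 ± 2.13 (adjusted p = 0.269 by edgeR). This value rested on MCF7 DMSO 2, with 6174657 reads against 6828 in MCF7 DMSO 1, and 114925 and 4430 in the treated libraries. By edgeR's quasi-likelihood test 0 of 565 features were called, 73 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 17. Without MCF7 DMSO 1 the count was 74, without MCF7 Akti 2 it was 8, and without either HCT116 DMSO library it was 3. Without the 3 libraries whose markers went against their labels it was 0.

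The MCF7 DMSO libraries differed from each other by an SD of 3 on the log2 scale over features. The SD was 2.46 between the MCF7 Akti libraries, 2.18 between the HCT116 Akti libraries and 0.5 between the HCT116 DMSO libraries. In MCF7 DMSO the log2 ratio, replicate 2 over replicate 1, rose with GC content across snoRNAs (Spearman's rho = 0.84) and miRNAs (rho = 0.66). Across snoRNAs rho was -0.53 in MCF7 Akti, -0.39 in HCT116 Akti and 0.58 in HCT116 DMSO. These correlations are across features, which are not independent replicates.

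**Figure D3:**
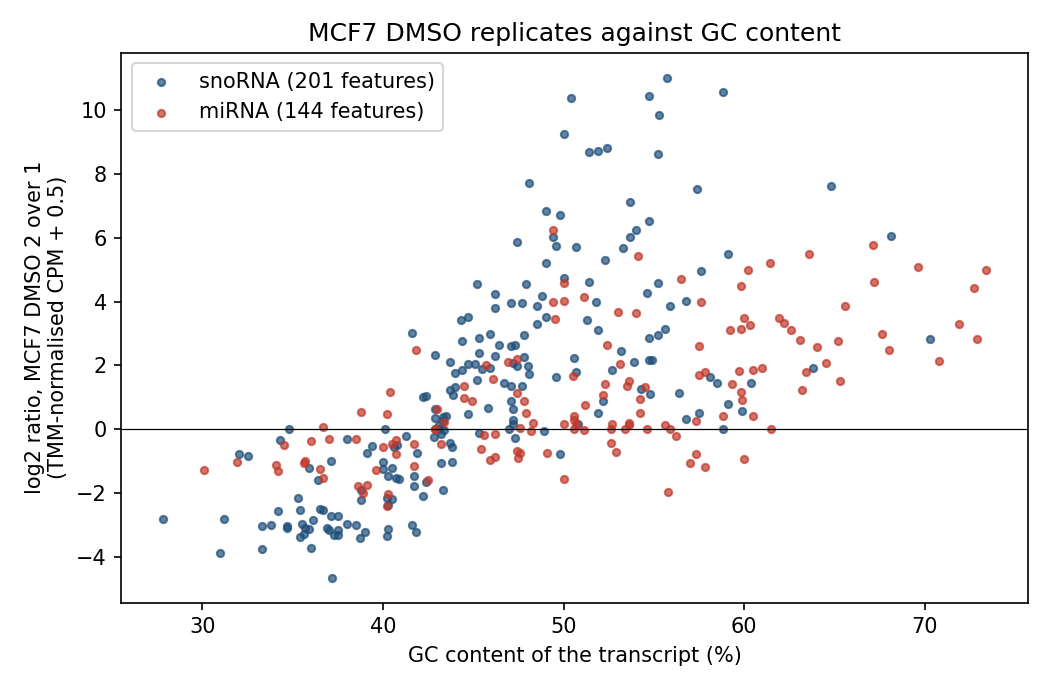
Log2 ratio of normalised CPM (plus 0.5) in MCF7 DMSO 2 over MCF7 DMSO 1 against the GC content of the transcript (%), 1 point per tested snoRNA or miRNA. The ratio is mostly below 0 at low GC content and above 0 at high GC content, with a Spearman's rho of 0.84 in snoRNAs and 0.66 in miRNAs.

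Among the fixed lists in MCF7, no member of any list passed over all features, and 1 list of 21 was called by camera. This was miR-10 and miR-196, miRNAs encoded in the HOX clusters, with all 3 tested members above 0 (adjusted p = 0.0112, and adjusted p = 0.859 with an estimated correlation). Its median log2 fold change was 6.76, or 3.26 with MIR196A1 at its bound, and 2 members passed adjusted over the list alone. All 3 had their highest MCF7 count in the library labelled MCF7 Akti 1, where the HCT116 markers were high too: MIR196A1 had 28 reads there and 0 in the other MCF7 libraries. The list of HCT116 markers had 2 tested members, MIR31 and MIR135B, and both passed adjusted over the list alone. Of miRNAs known to target AKT-mTOR genes, 1 of 6 (MIR100) passed adjusted over the list alone, and MIR99B, MIR375 and MIR99A had log2 fold changes of -4.09, -3.54 and -2.83. These 3 values rested on MCF7 DMSO 2, with 57527, 1022 and 614 reads there against 473, 15 and 65 in MCF7 DMSO 1. The miR-99/100-let-7-125 clusters had 1 of 9 members and the small Cajal body RNAs 1 of 13 past that threshold. It was 0 of 3 for the miR-17-92 cluster and its paralogs, 0 of 8 for let-7, 0 of 3 for miR-200, 0 of 4 for miR-15/16, 0 of 3 for miR-183, 0 of 4 for miRNAs known to target PTEN and 0 of 3 for hypoxia. It was also 0 of 4 for miR-23/27/24, 0 of 5 for miR-30, 0 of 6 for miR-181, 0 of 6 for MCF7 markers, 0 of 3 for Y RNAs and 0 of 3 for vault RNAs. In the larger classes it was 0 of 110 C/D box snoRNAs, 0 of 77 H/ACA box snoRNAs, 0 of 17 spliceosomal snRNAs and 0 of 11 ribosomal RNAs. The 3 tested members of the miR-17-92 list were MIR25, MIR93 and MIR106B, from a paralog. No gene of miR-17-92 itself was matched by symbol. The same 3 genes and MIR26A2 were the 4 tested for PTEN, so these lists are not separate results.

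With 1 tested member each, the lists of p53-responsive miRNAs (MIR107), inflammation (MIR146B), muscle, liver, endothelial and fibroblast markers (MIR126) and nervous system markers (MIR128-1) had log2 fold changes of -1.05, 0.01, 1.68 and -3.78 in MCF7. MIR126 had 288 reads in the library labelled MCF7 Akti 1 and 29, 29 and 35 in the other MCF7 libraries. The MIR128-1 value rested on MCF7 DMSO 2, with 497 reads against 10 in MCF7 DMSO 1, and 24 and 8 in the treated libraries. The lists of the miR-29 family, miRNAs of the 14q32 and chromosome 19 clusters, and blood cell markers had no tested member. The same held for the lists of GAS5 and SNHG1 snoRNAs, tRNAs, mitochondrial RNAs and histone genes. For the miR-29 family, the GAS5 and SNHG1 snoRNAs, tRNAs and mitochondrial RNAs, 0 listed features carried a member's symbol. MIR21 was not found by symbol either. Such RNAs may be among the IDs without a match, so these data do not show whether they were expressed. MIR210, a miRNA induced by hypoxia, had a log2 fold change of -3.43 ± 2.04 (SE), with 15 and 2 reads in the treated libraries and 0 and 194 under DMSO.

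In HCT116, the comparison asked which small RNAs changed with 20 µM Akti-1/2. SNORD45B was higher in the libraries labelled Akti, with 62144 and 199401 reads against 55 and 59 under DMSO (log2 fold change 15.36 ± 3.26 SE, adjusted p = 0.0375 by edgeR). It was also among the features that separated MCF7 DMSO from HCT116 DMSO. Next by unadjusted p came MIRLET7C at 9.86 ± 2.39, MIR10B at -8.9 ± 2.26 and MIR31 at -10.22 ± 2.67, each with an adjusted p of 0.0722 in edgeR's test. MIR31 had 3 reads in the treated libraries together and 24824 under DMSO, a ratio of summed normalised counts of 1030 (counting interval 352 to 4990). SNORD20, SNORD61, SNORD11 and SNORD90 had log2 fold changes of 7.1, 7.41, 6.05 and 6.25, and MIR100 and the unnamed ENSG00000265150.1 had -8.58 and -8.44. None of these 6 passed. SNORD104, SNORD43, SNORD68 and SNORD99, abundant under DMSO, had -4.84, -2.5, -5.06 and -2.01 and did not pass.

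By edgeR's quasi-likelihood test 1 of 565 features was called in HCT116, and 147 had an unadjusted p under 0.05, 50 higher and 97 lower. This balance turned with the method, to 86 higher and 80 lower with upper-quartile scaling, 104 and 78 with DESeq2, and 5 and 226 with total counts. The scaling mattered here: the median log2 fold change over all features was -1.31 with TMM and -4.36 with total counts. RLE and total-count scaling, the stricter CPM filter and limma-voom each called 0, while DESeq2 called 80 and the 4 HCT116 libraries alone 232 (76 higher, 156 lower). Leaving out 1 library gave 0 without any HCT116 library, 29 and 30 without MCF7 Akti 1 and 2, and 128 and 89 without MCF7 DMSO 1 and 2. MCF7 libraries are not part of this contrast but bear on its test through the dispersion, which all 4 groups share. The SD between replicates was 3 in MCF7 DMSO, 2.46 in MCF7 Akti, 2.18 in HCT116 Akti and 0.5 in HCT116 DMSO. The 1 call with all libraries and the 232 with HCT116 alone therefore rest on different estimates of spread. No fit without the 3 libraries in question was possible, because both HCT116 Akti libraries are among them.

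Among the lists in HCT116, camera called 2 of 21. The let-7 family, miRNAs that repress growth-promoting transcripts, had 7 of 8 tested members above 0, led by MIRLET7C at 9.86 and MIRLET7E at 3.33 (median 1.49, adjusted p = 0.0242, and adjusted p = 0.867 with an estimated correlation). The list's median lay 2.81 above the median of all features with TMM and 2.61 above it with total-count scaling, where the list's own median was -1.75. With DESeq2 it lay 3.04 above the median of the same 565 features, and 0.52 above that of all 3993 features of that fit. MIRLET7C alone passed adjusted over the list alone, and it is a feature that separated the lines under DMSO. H/ACA box snoRNAs, which guide pseudouridylation, had 17 of 77 members above 0 (median -2.79, or -1.83 with members of a group at 0 at their bound, adjusted p = 0.0242, and adjusted p = 0.867 with an estimated correlation). Their median lay below that of all features by a log2 difference of -1.48 with TMM or upper-quartile scaling and -1.42 with RLE or total counts. With DESeq2 the difference was -1.43 over the same 565 features and -3.95 over all 3993. Adjusted over the list alone, 0 members passed. The GC trend of the snoRNAs moved with the labels here: Spearman's rho of each library's deviation against GC content was -0.63 and -0.66 in the HCT116 Akti libraries and 0.6 and 0.69 in HCT116 DMSO. It did not follow treatment in MCF7, at 0.06 and -0.7 in Akti 1 and 2 and -0.66 and 0.8 in DMSO 1 and 2. With the GC offset camera at the preset correlation called both lists (adjusted p = 0.00473 for let-7 and 0.000588 for H/ACA box snoRNAs). SNORD45B went from 15.44 ± 3.33 without the offset to 11.28 ± 2.37 with it (log2 fold change with SE, features with a GC value). Its adjusted p was 0.107 in edgeR's test, so 0 features were called. The fold and its derived error fell together, while the unadjusted p rose from 8.54e-05 to 0.000417 in edgeR's test. The lost call therefore does not show that GC content accounts for SNORD45B. The offset with the replicate block called 17, and there SNORD45B had 10.81 ± 1.64 (adjusted p = 3.05e-08 in edgeR's test). The labels give no batch shared by libraries of the same replicate number, so the blocked fit adds no support for SNORD45B. SNORA18, SNORA2C and SNORA31 had log2 fold changes of -2.73, -5.93 and -2.48, and SNORA53 had 0.3.

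Further HCT116 lists had members that passed adjusted over the list alone, and of these only SNORD45B passed over all features. Vault RNAs had 3 of 3, with VTRNA2-1 at 566 and 1119 reads under DMSO and 0 in both Akti libraries (at least 69.8-fold lower, against a floor of 3 counts over the group). VTRNA2-1 also had 52 reads in the library labelled MCF7 Akti 1 and 0 in the other MCF7 libraries. The HCT116 markers had 2 of 2, the miR-99/100-let-7-125 clusters 3 of 9 and miR-10 and miR-196 1 of 3 (MIR10B). It was 1 of 6 for miRNAs known to target AKT-mTOR genes (MIR100) and 1 of 1 for muscle and endothelial markers (MIR126, log2 fold change -4.56). For a list of 1 member this is the unadjusted p, 0.0375 in edgeR's test. MIR10B, MIR100 and MIR126 had 65748, 23052 and 288 reads in the library labelled MCF7 Akti 1. In HCT116 Akti 1 and 2 they had 16 and 11, 7 and 8, and 4 and 0 reads. This is the pattern of the line features that went against the labels. C/D box snoRNAs had 1 of 110, the called SNORD45B. The count was 0 for the miR-17-92 paralogs MIR25, MIR93 and MIR106B, miR-200, miR-15/16, miR-183, miRNAs known to target PTEN, hypoxia, miR-23/27/24 and miR-30. It was also 0 for miR-181, MCF7 markers, Y RNAs, small Cajal body RNAs, spliceosomal snRNAs and ribosomal RNAs. The same held for MIR107, MIR146B and MIR128-1, each the lone tested member of its list. Among the members of these lists, MIR190B had 5.91 ± 2.29, RNY4 3.28 ± 1.62, MIR375 -1.97 ± 1.86 and RNU5A-1 0.65 ± 1.42 (log2 fold change with SE). MIR210 had 0 reads in both treated libraries and 78 and 128 under DMSO (at least 8.54-fold lower).

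The test of whether the Akti-1/2 effect differed between the lines called 15 of 565 features, 12 with a lower and 3 with a higher effect in HCT116. MIR31, MIR100, MIR10B, SNORD54 and SNORD14D had the lower effect in HCT116, and SNORD45B and MIRLET7C the higher. SNORD14D had 4930 and 7460 normalised CPM in HCT116 DMSO, 98.7 and 24.2 in HCT116 Akti, 28.2 and 125 in MCF7 DMSO, and 6780 and 51.5 in the libraries labelled MCF7 Akti 1 and 2. These features were high in the library labelled MCF7 Akti 1 and both HCT116 DMSO libraries, or low in those 3, which is the pattern of the line features that went against the labels. Without the library labelled MCF7 Akti 1 the count was 0, and it was 0 without either HCT116 Akti library. It was 52 without MCF7 Akti 2, 35 and 66 without MCF7 DMSO 1 and 2, and 7 and 6 without HCT116 DMSO 1 and 2. RLE scaling called 3, and total-count scaling, the stricter CPM filter and limma-voom called 0.

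Averaged over both lines, Akti-1/2 gave 7 called features, 6 lower and 1 higher (SNORD45B), each at an adjusted p of 0.0324 by edgeR. The SNORD45B value came from HCT116, with 15.36 ± 3.26 there and -0.59 ± 1.87 in MCF7 (log2 fold change with SE). SNORD55, SNORD105B and SNORA2C had log2 changes of -8.02 ± 1.81, -6.76 ± 1.6 and -6.51 ± 1.6 (SE). SNORD105B had 83121 reads in MCF7 DMSO 2 and 14 in MCF7 DMSO 1, and 348 and 16 in the libraries labelled MCF7 Akti 1 and 2. SNORD3A, outside the rule for named genes and chosen after its values were seen, had 973 and 0 reads in MCF7 DMSO 2 and 1. The other 2 lower features carry IDs without a matched name (ENSG00000265150.1 and ENSG00000258486.2). RLE and total-count scaling, the stricter CPM filter, limma-voom and the GC offset each called 0. Leaving out 1 library gave 150 and 1 without MCF7 DMSO 1 and 2, 57 without MCF7 Akti 1, 0 without either HCT116 Akti library and 11 without HCT116 DMSO 1.

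The features called in MCF7 and HCT116 did not overlap, since MCF7 had 0 calls. At an adjusted p under 0.1 in edgeR's test the counts were 0 and 6, so overlap could not be tested, and with DESeq2 4 features were called in both lines. Without MCF7 DMSO 1, 22 features were called in both lines. Across the 565 features the log2 fold changes of the lines had Pearson's r = -0.01 and Spearman's rho = 0.07, and 51.2% had the same sign. Without the library labelled MCF7 Akti 1 r was 0.46, and without MCF7 DMSO 2 it was -0.62. Features are not independent replicates.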

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

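The test of the difference between the lines was fixed before the data were examined. The tests of explanations in this part were chosen after the results they bear on had been seen. The bounds used for the line features, at least 21 of 28 for an exchanged library and at most 7 of 28 against it, and the 10% bound for a mixture were also set with the counts known, so they describe these libraries and do not test a prediction.

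The test of the difference between the lines singled out 15 features whose Akti-1/2 effect differed. The fitted log2 difference, HCT116 minus MCF7, was -21.34 for MIR31, -20.02 for MIR100, -15.93 for MIR10B, -13.44 for SNORD54 and -12.14 for SNORD14D, and 15.95 for SNORD45B and 10.85 for MIRLET7C. Groups with counts of 0 to 3 enter some of these, whose size depends on the prior count.

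These differences follow the line features that went against the labels. In the library labelled MCF7 Akti 1, an effect of Akti-1/2 is argued against by the other MCF7 Akti library, which had 0 of 28 line features on the HCT116 side. A mixture with a large share of MCF7 RNA is argued against by the MCF7-high features, at a median of 6.08% of their MCF7 DMSO level, against 1.96% and 1.29% in the HCT116 DMSO libraries. Among the 10 such features MIRLET7C and SNORD45B stood at 0.102% and 0.0361% of their MCF7 DMSO level, and the highest value of these 2 in the HCT116 DMSO libraries was also 0.102%. The others ran from 3.66% (MIR454) to 13.3% (SNORD61). These percentages use TMM, and the median depends on that scaling. By gene counts SNORD61 took 14.95% of the library labelled MCF7 Akti 1 and 55.49% of MCF7 DMSO 1. MIRLET7C stayed low by gene counts too, at 0.691 CPM there against 245 and 345 in MCF7 DMSO. A wrong or exchanged label remains a candidate explanation, with 23 of 28 features on the HCT116 side. Over all tested features the library labelled MCF7 Akti 1 had Pearson's r of 0.953 and 0.934 with HCT116 DMSO 1 and 2. With MCF7 Akti 2, MCF7 DMSO 1 and MCF7 DMSO 2 r was 0.878, 0.88 and 0.822.

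For the libraries labelled HCT116 Akti, at most 6 of 28 features lay on the HCT116 side. An effect of Akti-1/2 and a wrong label cannot be told apart, because both treated libraries moved and no other HCT116 Akti library exists to compare. Over all tested features HCT116 Akti 1 had Pearson's r of 0.955, 0.954 and 0.836 with MCF7 DMSO 1, MCF7 Akti 2 and MCF7 DMSO 2. With HCT116 DMSO 1 and 2 r was 0.866 and 0.841. For HCT116 Akti 2 the values were 0.909, 0.902 and 0.683, and 0.751 and 0.723. Both explanations allow such values. The HCT116-high features stood at a median of at most 2.15% of their HCT116 DMSO level. The share of HCT116 RNA cannot be judged from this, since Akti-1/2 itself may have lowered these features. A wrong or exchanged label needs both kinds of line feature on the MCF7 side. At least 22 of 28 features lay there. In HCT116 Akti 2, however, only 5 of the 10 MCF7-high features did, at a median of 18.9% of their MCF7 DMSO level. Neither count is a clean test of the label in HCT116 Akti 2. There miRNAs made up 0.0987% and H/ACA box snoRNAs 0.0124% of the gene counts, against means of 4.23% and 0.671% in HCT116 DMSO. Line features of these classes may be low there whatever the line. With TMM, MIRLET7C and SNORD45B stood at 64.7% and 77.3% of their MCF7 DMSO level in HCT116 Akti 1 and 108% and 1160% in HCT116 Akti 2. These values depend on the scaling. As CPM of the gene counts MIRLET7C had 138 and 74.3 in HCT116 Akti, 245 and 345 in MCF7 DMSO, and 1.3 and 1.26 in HCT116 DMSO. The lncRNAs DSCAM-AS1 (29 and 48 reads) and LINC00052 (6 and 64), chosen after their values were seen, had 0 reads in both HCT116 DMSO libraries. In HCT116 Akti 1, 9 of the 10 MCF7-high features lay on the MCF7 side. There 4 of the 18 HCT116-high features, all H/ACA box snoRNAs, stayed on the HCT116 side. SNORA53 stayed above its level in MCF7 DMSO in both HCT116 Akti libraries. With TMM it matched HCT116 DMSO, while as CPM of the gene counts it had 95.5 and 25.4 against 418 and 525. Only this match depends on the scaling. The distance from MCF7 DMSO, which bears on the label, held by gene counts too, with 0.55 and 0.714 CPM there. SNORA53 is 1 feature, set out after its values were seen. An exchange of line labels within the series pairs libraries, and 3 libraries were out of place, so 1 exchange alone would leave a library unexplained. The libraries were kept under their labels in all comparisons.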

How the results depend on the processing

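Alternatives with a GC term, the fit on features with a GC value and the fit without 3 libraries were chosen after seeing the data. Where no cause is named, the cause was not tested. Counts are of called features, in the order MCF7, HCT116, difference, averaged effect, HCT116 against MCF7 under DMSO, against 0, 1, 15, 7 and 4.

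RLE scaling gave 0, 0, 3, 0 and 0, total counts 0 in all 5, and upper-quartile scaling 5, 19, 33, 22 and 100. Higher calls made up 14 of 19 in HCT116 and 74 of 100 between the lines with upper quartile. No filter gave 3, 5, 10, 14 and 5, and the CPM filter 0 in all 5, with 287 features. DESeq2 gave 17 (6 higher), 80 (47 higher), 26 (14 higher), 57 (10 higher) and 45 (18 higher), and limma-voom 0, 0, 0, 0 and 13. miRNAs alone gave 0, 0, 20, 0 and 21. Fits of one line or of the DMSO libraries alone gave 0 in MCF7, 232 in HCT116 and 98 between the lines. The GC offset gave 0, 0, 4, 0 and 0, and features with a GC value without it 0, 1, 13, 5 and 4. Without the 3 libraries whose markers went against their labels the count was 0 in MCF7 and 98 between the lines. Summing copies left all 5 counts as they were.

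The replicate block gave 1, 3, 13, 3 and 4, and with the GC offset 1, 17, 19, 10 and 21. The numbers do not pair the samples: the labels state no shared batch, and deviations of same-numbered libraries correlated from -0.44 to 0.45 over 6 pairs of groups.

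Leaving out 1 library gave 0 to 74 in MCF7, 0 to 128 in HCT116, 0 to 66 for the difference, 0 to 150 for the averaged effect and 0 to 108 between the lines. In the same order, the counts were 0, 29, 0, 57 and 108 without MCF7 Akti 1, and 8, 30, 52, 9 and 108 without MCF7 Akti 2. They were 74, 128, 35, 150 and 107 without MCF7 DMSO 1, and 0, 89, 66, 1 and 25 without MCF7 DMSO 2. Without HCT116 Akti 1 all 5 were 0, and without HCT116 Akti 2 they were 0, 0, 0, 0 and 45. They were 3, 0, 7, 11 and 2 without HCT116 DMSO 1, and 3, 0, 6, 8 and 2 without HCT116 DMSO 2. The lone library left in a group was assumed to vary like the others.

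Of lists, 3 were called, against 1 with the CPM filter, 1 with miRNAs alone, 0 with an estimated correlation, 0 with fry and 2 to 4 without 1 library. The overlap of calls was 0, against 4 with DESeq2 and 0 to 22 without 1 library (22 without MCF7 DMSO 1, 0 for each other library).

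Of 4123 alternative values of the named features, 3724 stayed on their side of the threshold, 142 lost a call, 257 gained one and 0 called values changed sign, while 322 uncalled values did. At the spread of these libraries, simulated changes of 32-fold were recovered in 11% of the 100 features so changed for MCF7 and 10% for HCT116. For 4-fold changes it was 0% and 1% of 100. The simulated sets had 565 features.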

Other observations

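The comparison for the averaged effect was fixed before the data were examined. The tests of explanations in this part were chosen after the results they bear on had been seen.

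Among the Y RNAs, small RNAs bound by the Ro60 protein, RNY4 had 70.7 and 1320 normalised CPM in the libraries labelled MCF7 Akti 1 and 2, 854 and 356 in MCF7 DMSO, 459 and 117 in HCT116 Akti and 28.8 and 30.5 in HCT116 DMSO. RNY1 had 132 and 131 in MCF7 Akti and 93.5 and 205 in MCF7 DMSO. The lncRNA DSCAM-AS1, chosen after its values were seen, had 42, 42 and 33 reads in MCF7 Akti 2 and MCF7 DMSO 1 and 2, 29 and 48 in the libraries labelled HCT116 Akti, and 0 in MCF7 Akti 1 and both HCT116 DMSO libraries.

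The spread between the MCF7 DMSO libraries followed GC content, a candidate source being GC-dependent recovery or amplification: Spearman's rho of the log2 ratio against GC was at least 0.66 in both snoRNAs and miRNAs. Depth is argued against, since the gene counts of replicate 1 over replicate 2 stood at 1.06. An exchanged treatment label cannot be told apart from other sources: MCF7 DMSO 1 correlated with MCF7 Akti 2 at r = 0.99, but its possible partner, the library labelled MCF7 Akti 1, correlated with MCF7 DMSO 2 at 0.822 and carried the other line's markers. No biological explanation was tested, since both libraries have the same labels.

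For the averaged effect, the 18 splits with 2 libraries of each line on each side are too few for a share under 0.05. In the model of the report the real split called 7 features, 4 of the 18 splits (the real one included) called at least as many, and the highest other called 257. One of these 4 set both MCF7 Akti and both HCT116 DMSO libraries against the rest and called 15. It keeps the treatment groups whole and is the test of the difference between the lines, not an unrelated grouping. In a simpler model with the line as a term the real split called 0 features, so that all 34 splits gave as many says nothing about the 7, and the highest other called 259. In both models the highest split set MCF7 Akti 1, MCF7 DMSO 2 and both HCT116 DMSO libraries against the rest, which points to a structure of the samples other than treatment. In that order their snoRNA deviations had a Spearman's rho against GC of 0.06, 0.8, 0.6 and 0.69. In the rest rho ran from -0.7 to -0.63. The miRNA share was 2.34% to 4.34% on that side and 0.0987% to 1.04% in the rest. The split thus went with GC trend and composition, whose cause was not tested. Of the 7 features, 5 had a GC value, and with the GC offset each went from an adjusted p of at most 0.0421 to 0.304 in edgeR's test. SNORD55 went from -8 ± 1.8 to -6.55 ± 1.85, SNORD45B from 7.46 ± 1.78 to 4.85 ± 1.28, SNORD105B from -6.72 ± 1.61 to -5.33 ± 1.49, SNORA2C from -6.5 ± 1.61 to -5.63 ± 1.58 and SNORD3A from -9.12 ± 2.21 to -8.71 ± 2.27 (log2 change with SE). The calls ended as the smallest unadjusted p of the 5 rose from 0.000143 to 0.00222. All 5 folds were smaller, while the errors moved both ways.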
